A study of Mus musculus with 16 samples.

How the data were processed

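The series measured, by chromatin immunoprecipitation followed by sequencing (ChIP-seq), where 4 transduced transcription factors were bound in mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos. Each culture was infected with Foxa1, Foxa2, Foxa3 or Hnf4a, and chromatin was precipitated on day 2 or day 30 with an antibody to that same factor. Of the 16 samples, 8 were ChIP samples, each with 1 deposited peak list, and 8 were input samples, which were not used here. Groups were taken from the titles and the antibody and infection labels. There was 1 ChIP sample per factor and day, so no value of a factor and day carries an error between samples. The tests compare lists of peaks, not conditions, except 1 test of peak counts between days, paired over the 4 factors.

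The submitters' processing notes name BWA 0.6.2, MACS2 2.1.0, bedtools 2.16.2 and the mouse build mm9, without the role or order of the tools, the peak threshold or the way the inputs entered. Each list was deposited as a table without a header, with a chromosome, a start, an end, a name and a score per peak. The deposited score was read as −log10 of a p-value, from the values: every score lies above 5, and many equal −log10 of a Poisson upper tail to the precision of the file. Scores are the authors' own. In the comparisons they were used to rank or filter peaks within a list, and in the closing section also to estimate a background rate per list. Start and end positions are given 1-based on mm9. Read depth is not given in the lists and remained unknown. The annotation at hand was of another build, so no peak was assigned to a gene, start site or motif, and the planned counts near start sites, near fixed gene lists (hepatocyte, liver transcription factor, epithelial, intestinal, fibroblast, neuronal, macrophage, endothelial and muscle genes) and with factor motifs were not run.

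Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1 was used for all calculations, and Matplotlib 3.10.9 for the figures. For each of the 28 pairs of lists, the peaks of the shorter list that overlapped the longer list by at least 1 bp were counted and set beside 1000 random placements of those peaks on the same chromosome, a permutation of positions. Chromosome length was taken as the largest peak end over the 8 lists. The one-sided p is the share of placements with as many overlaps, of which 0.001 is the smallest this test can give, and p-values were adjusted by the Benjamini-Hochberg method over the 28 pairs. Placement on the whole chromosome ignores that mappable and open chromatin is limited, so it sets a low bar. The number of regions that independent lists would share among the merged regions of all lists, the product of both region counts over the total, is given as well. That total holds only regions in at least 1 list and is mostly made of Foxa1 day 30 regions. The number is therefore raised for every pair, most of all for pairs with that list. A count below it does not show that 2 lists avoid each other. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only.

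Peaks of all lists were merged where they overlapped or touched. A region was called recurrent when it lay in a Foxa and a Hnf4a list or in 4 or more lists. The regions named in the text were set by a rule: the 3 peaks with the highest score in each list, the 3 regions in the most lists, and the 3 highest-scoring regions listed on both days of each factor. Other regions named, such as blocks of peaks, were chosen after their values were seen, and the text says so. The overlap counts were tested on simulated lists of the sizes of Foxa3 day 2 and Foxa1 day 30. Of 50 pairs without planted overlap 1 passed 0.05, and 50 of 50 pairs with 10 planted shared peaks did. The simulated peaks were spread at random over the chromosomes, as the placement test itself assumes. These runs check the counting, and not the error rate on clustered lists such as the real Foxa3 day 2 list.

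Alternatives fixed before the data were examined were a stricter score threshold of 15.07, 2 times the highest of the lists' lowest scores; merging of peaks within 500 bp; leaving out mitochondrial, random and unplaced sequences; leaving out recurrent regions; an overlap of 50% of the shorter peak; peak centres within 500 bp; equal numbers of peaks by score; and rotation of a list around each chromosome in place of random placement. For overlaps between factors, the recurrent regions left out were those in 4 or more lists only. Chosen after the data were seen were the removal of dense blocks (peaks of all lists chained over gaps of up to 20 kb, with 10 or more peaks), the removal of blocks with over 3 peaks per kb, the pair of Foxa3 day 2 with Hnf4a day 30, the splits by score, the Fisher tests of shares and their repeat with day 30 lists reduced to the day 2 number of peaks or to a common 174, an exact sign-flip permutation test of the log2 count ratios of the days paired by factor, and the estimate of a background rate from the scores. That rate was the lowest rate, not a whole number, whose Poisson tails matched at least 3 distinct scores and 10% of peaks within 8e-05. It was the third rule tried. For the long Foxa1 day 30 list it used the first 600 peaks by position. On simulated scores modelled on the Foxa1 day 2 list the rule recovered 10 of 10 rates. Most simulated peaks shared a common rate, and fewer scores were passed than that list holds. The runs thus do not test lists where fewer peaks share a rate, such as Foxa1 day 30, with 38.5% of the peaks used.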

Results

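Binding of 4 transduced transcription factors was mapped by ChIP-seq in mouse embryonic fibroblasts of the C57BL/6 strain, taken from embryos at 13.5 days post coitum. Foxa1, Foxa2 and Foxa3 are forkhead proteins that bind DNA in liver and other endoderm-derived tissues, and Hnf4a is a nuclear receptor of hepatocytes. Each factor was introduced alone and precipitated with its own antibody on day 2 and on day 30. The 8 peak lists held 4839 peaks in total. None lay on the Y chromosome, on mitochondrial DNA or on random or unplaced sequences. Read depth was unknown, there were no replicates, and positions are on mm9 without gene assignment.

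The first comparison was of how many sites each factor had at the early and the late day. Every factor had more listed peaks on day 30 than on day 2. Foxa1 had the most on day 30, 3331 peaks against 442 on day 2, a ratio of 7.54. Foxa2 had far fewer peaks, 174 against 23, with a similar ratio of 7.57. Foxa3 had 265 against 146, a ratio of 1.82, and Hnf4a had 448 against 10, a ratio of 44.8. The Foxa1 day 30 peaks covered 496.5 kb, and the Foxa1 day 2 peaks 45.2 kb. The remaining day 30 lists covered 16.05 kb for Foxa2, 70.25 kb for Foxa3 and 44.98 kb for Hnf4a. The median peak was 119 bp wide for Foxa1 day 30 and 82 bp for Foxa1 day 2. Foxa3 day 30 peaks were the widest, with a median of 237 bp against 78.5 bp on day 2. The shortest Foxa3 day 30 peak was already 175 bp, against 49 to 76 bp in the other lists, so the minimum width of that list enters its median and covered length. Paired over the 4 factors, the mean log2 ratio of counts was 3.04, higher on day 30 in 4 of 4 (two-sided exact sign-flip p = 0.125, the smallest that 4 pairs allow, so the test cannot reach 0.05). At the stricter score threshold Hnf4a kept 5 day 2 peaks and 1 day 30 peak, a ratio of 0.2, so its direction turned, while the ratio was 26.4 for Foxa1, 5 for Foxa2 and 22.5 for Foxa3, whose day 2 list kept 2 peaks. Foxa3 had 47 day 2 peaks once the 2 densest blocks of peaks, on chromosomes 9 and 2, were left out, a ratio of 5.64, and its ratio was 3.38 without recurrent regions, 4.11 with peaks within 500 bp merged and 7.41 without dense blocks.

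**Figure D1:**
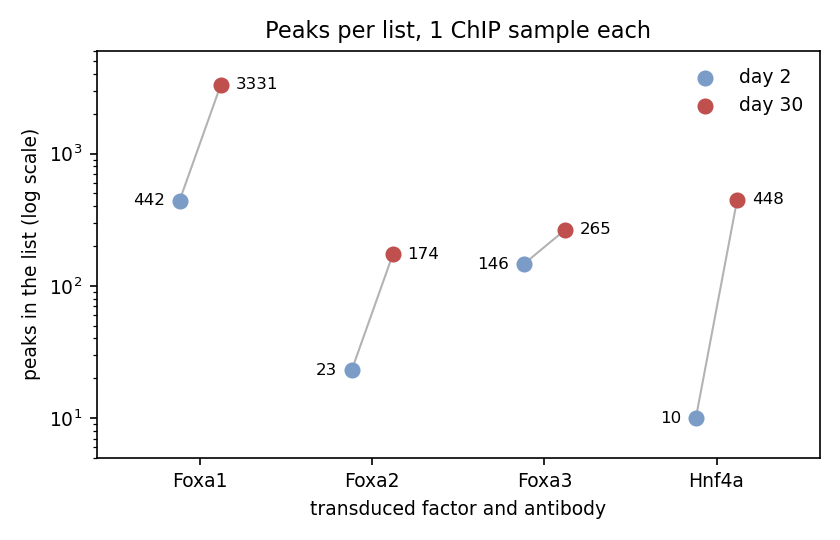
Number of peaks in each list on a log axis, by transduced factor, for day 2 (blue) and day 30 (red); each point is 1 ChIP sample and has no error bar. The day 30 point lies above the day 2 point for each factor, from 442 to 3331 for Foxa1 and from 146 to 265 for Foxa3.

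The second comparison asked whether sites listed early were listed again late. Most Foxa1 sites were: 312 of 442 day 2 peaks (70.6%, interval 66.1 to 74.8%) overlapped a day 30 peak. For Foxa2 the number was 11 of 23 (47.8%, 26.8 to 69.4%), and for Foxa3 27 of 146 (18.5%, 12.6 to 25.8%). None of the 10 Hnf4a day 2 peaks was listed again, which allows a share of up to 30.9%. Random placement gave a mean of at most 0.143 overlapping peaks for these pairs. The adjusted placement p was 0.002 for each Foxa protein and 1 for Hnf4a. Among merged regions, Foxa1 shared 293 between days, below the 347.2 of independent lists, Foxa2 shared 12 against 0.966, and Foxa3 shared 23 against 9.10. With the day 30 list reduced to its 442 highest-scoring peaks, the Foxa1 share was 40.5%, with the 174 highest-scoring it was 22.6%, and with equal numbers the Foxa2 share was 21.7%. The Foxa3 share was 30.4% of 69 peaks without recurrent regions, 44.1% of 34 without dense blocks of peaks, and 57.4% of 47 without the 2 densest, which hold no Foxa3 day 30 peak, so that their removal could only raise it.

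The 3 highest-scoring Foxa1 peaks of each day were listed on both days, and most of them in other Foxa lists too. This did not hold for high scores in general. In the highest of 4 score groups of Foxa1 day 30, 24.1% of 843 peaks overlapped Foxa1 day 2. A region on chromosome 17 (35848391 to 35849101) had the highest score on day 30, 107.1, and the second highest on day 2, 67.6. A region on chromosome 10 (86307319 to 86309322) had the highest day 2 score, 80.2, and scored 78.3 on day 30. It also held the strongest Foxa2 day 2 peak, with a score of 25.3. A region on chromosome 4 (3733814 to 3735332) scored 30.5 on day 2 and 59.8 on day 30. The third-highest Foxa1 day 2 peak, on chromosome 6 (113960851 to 113961995, score 46.1), was listed on both days for Foxa1 and in no list of another factor. For Foxa2, a region on chromosome 13 (99584964 to 99585212) scored 9.85 on day 2 and 33.6 on day 30, and one on chromosome 1 (36568510 to 36568647) scored 8.63 and 19.6. The strongest Foxa3 regions of both days were on chromosome 12 (55839093 to 55839773), with a day 30 score of 32.7, and on chromosome 11 (87236219 to 87236808), with 30.1. The third, on chromosome 12 (55811150 to 55811844, day 30 score 29.1), was also in the Hnf4a day 30 list. None of these 3 was in a Foxa1 or Foxa2 list, and all 3 lie in blocks of several Foxa3 peaks. The highest-scoring Foxa3 day 30 peak, on chromosome 4 (56115184 to 56115572, score 32.85), was in both Foxa1 lists. It was not listed for Foxa3 on day 2. Because depth is unknown, scores from different lists can show neither a change in binding nor its absence.

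Foxa1 day 2 peaks with a score above the median of 8.20 were listed again more often than the rest. The counts were 173 of 215 (80.5%) and 139 of 227 (61.2%), with a two-sided Fisher's exact p of 1.04e-05. Of the 3331 Foxa1 day 30 peaks, 3037 (91.2%) overlapped no day 2 peak. Those peaks had a median width of 116 bp and a median score of 10.2, against 189 bp and 18.5 for the 294 that did overlap. The split at the median score was chosen after the data were seen.

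The third comparison asked which sites the factors shared on the same day. On day 30 the Foxa2 and Foxa3 sites lay mostly within the larger Foxa1 list. Of the Foxa2 peaks, 154 of 174 (88.5%, 82.8 to 92.8%) overlapped a Foxa1 peak, and of the Foxa3 peaks 181 of 265 (68.3%, 62.3 to 73.9%). Foxa2 and Foxa3 shared less with each other, 39 of 174 Foxa2 peaks (22.4%, 16.5 to 29.3%). That share was 10.3% of 145 without regions in 4 or more lists, a setting that removes regions for being shared. It was 0% of 10 at the stricter threshold. On day 2, 9 of 23 Foxa2 peaks (39.1%) and 7 of 146 Foxa3 peaks (4.79%) overlapped Foxa1, and 1 of 23 Foxa2 peaks overlapped Foxa3. Each of these 6 pairs had an adjusted placement p of 0.002. Against independent lists, the day 30 Foxa2 and Foxa1 lists shared 150 regions against 139.5, Foxa3 and Foxa1 181 against 217.5, and Foxa2 and Foxa3 38 against 11.1. At day 2 these values were 9 against 2.40 for Foxa2 with Foxa1 and 8 against 14.5 for Foxa3 with Foxa1. For Foxa2 with Foxa3 they were 1 against 0.79, so that pair rests on 1 peak. Across days, 18 of 23 Foxa2 day 2 peaks (78.3%) overlapped Foxa1 day 30. Over all days, 15 of 15 pairs of Foxa lists had an adjusted placement p under 0.05, some of them with small overlaps. Foxa3 day 2 with Foxa1 day 30 had 4 of 146 peaks, and 4 shared regions against 114.1 of independent lists. Foxa3 day 2 with Foxa2 day 30 had 1 of 146, and 2 against 5.84. With the longer list reduced to as many peaks as the shorter by score, the shares in Foxa1 day 30 fell to 40.8% for Foxa2 and 29.4% for Foxa3. On day 2 the shares in Foxa1 were then 13.0% for Foxa2 and 1.37% for Foxa3, and 0% of Foxa2 peaks overlapped Foxa3. With centres within 500 bp, the day 2 shares in Foxa1 were 47.8% for Foxa2 and 12.3% for Foxa3. The Foxa3 overlap was no longer past 0.05 at the stricter threshold, with 2 peaks left. The Foxa2 overlap was no longer past it without regions in 4 or more lists, with 13 peaks left.

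**Figure D2:**
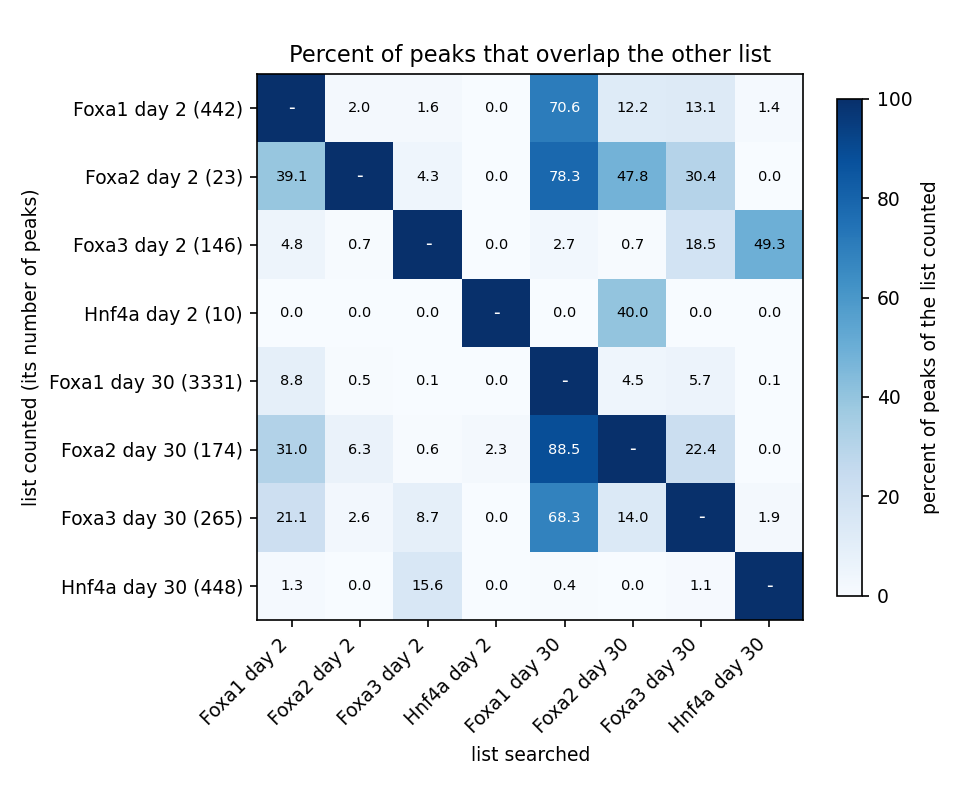
Percent of the peaks of the list in each line (its number of peaks in parentheses) that overlap the list in each column by at least 1 bp; darker blue is a higher percent. The Foxa1 day 30 column is dark for Foxa1 day 2 (70.6%), Foxa2 day 2 (78.3%), Foxa2 day 30 (88.5%) and Foxa3 day 30 (68.3%), and the Hnf4a day 30 column only for Foxa3 day 2 (49.3%).

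Sharing within the Foxa1 day 30 list was concentrated at its highest-scoring peaks. In the highest of 4 score groups of similar size, 124 of 843 peaks (14.7%, 12.4 to 17.3%) overlapped Foxa2 day 30, against 3 of 832 (0.361%, 0.0744 to 1.05%) in the lowest. For Foxa3 day 30 the shares were 15.5% and 1.44%, and for Foxa1 day 2 they were 24.1% and 2.2%. The groups also differed in median width, 167 bp in the highest and 105 bp in the lowest, and a wider peak has more room to overlap.

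**Figure D3:**
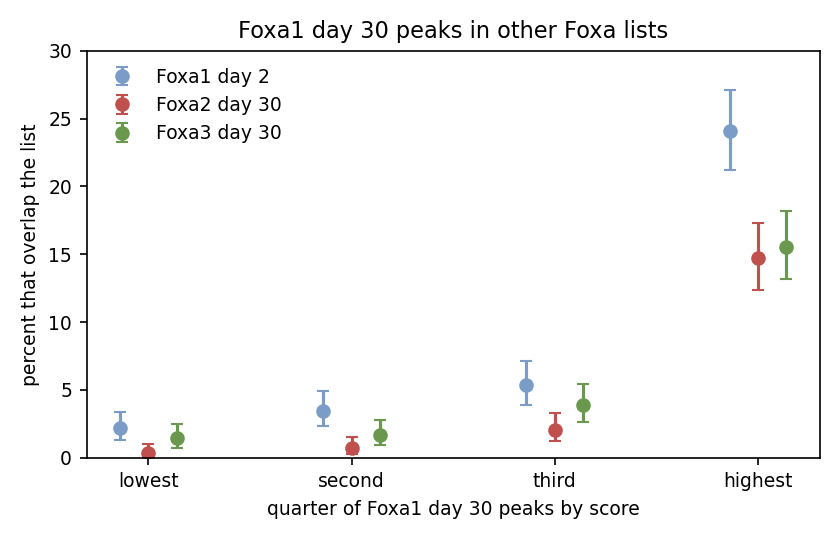
Percent of Foxa1 day 30 peaks that overlap the Foxa1 day 2, Foxa2 day 30 and Foxa3 day 30 lists, in 4 groups of peaks from the lowest to the highest score; bars are exact Clopper-Pearson 95% intervals. The highest group stands above the others, at 24.1%, 14.7% and 15.5%.

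Few Hnf4a peaks overlapped a Foxa list of the same day. Depth is unknown, so a site missing from a list is not shown to be unbound. On day 30, 2 of 448 Hnf4a peaks (0.446%, 0.0541 to 1.60%) overlapped Foxa1, with a placement mean of 0.163 and an adjusted p of 0.015. Independent lists would share 366.1 regions, and 2 were shared, but that number is raised by its total and does not show avoidance. Of the Foxa3 peaks, 5 of 265 (1.89%) overlapped Hnf4a (adjusted permutation p = 0.002; 5 shared regions against 29.2), and of the Foxa2 peaks 0 of 174, which allows a share of up to 2.1% (adjusted placement p = 1). On day 2, none of the 10 Hnf4a peaks overlapped a Foxa list of that day. The strongest Hnf4a day 30 peaks were on chromosome 7 (26022999 to 26023080, score 15.3), on chromosome 9 (3030159 to 3030216, score 14.8) and on chromosome 6 (51121807 to 51122099, score 14.2). The region on chromosome 9 was also in the Foxa3 day 2 list and lies in a dense block of peaks, described below. Of 12 pairs of a Foxa and a Hnf4a list, 5 had an adjusted placement p under 0.05. The share of Hnf4a day 30 peaks at Foxa1 day 30 was 2.23% with centres within 500 bp (permutation p by placement = 0.001, the smallest possible). It was 0.548% without the 2 densest blocks (0.007), 0.328% without dense blocks (0.102) and 0.224% without regions in 4 or more lists (0.142). The call was lost in the last 2 of these settings, and at the stricter threshold, which left 1 Hnf4a peak.

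The largest overlap of a Hnf4a list with a Foxa list was across days, and it was picked out after the data were seen. Most of it lay in dense blocks of peaks and may come from reads piled up there, as described below. Of the Foxa3 day 2 peaks, 72 of 146 (49.3%, 41 to 57.7%) overlapped the Hnf4a day 30 list, with 70 shared regions against 15.3 for independent lists. A block at the start of chromosome 9 (3000026 to 3038273) held 92 Foxa3 day 2 peaks (63.0% of that list) and 74 Hnf4a day 30 peaks (16.5%). It also held 4 Foxa1 day 2 peaks and none of the other 5 lists. A block on chromosome 2 (98502420 to 98507457) held 7 Foxa3 day 2 peaks, 9 Hnf4a day 30 peaks and 1 Foxa1 day 2 peak. In 9 such dense blocks lay 76.7% of the Foxa3 day 2 peaks and 31.9% of the Hnf4a day 30 peaks, and at most 4.91% of any other list. Outside the 9 blocks, 4 of 34 Foxa3 day 2 peaks (11.8%) overlapped Hnf4a day 30, and with equal numbers of peaks by score the share was 21.9% of 146.

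**Figure D4:**
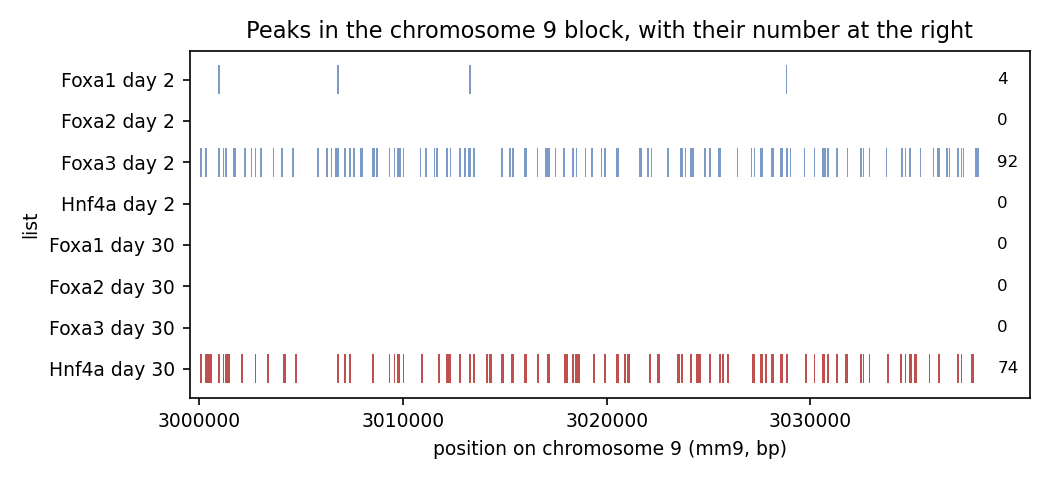
Peaks of the 8 lists along the block at the start of chromosome 9 (position in bp on mm9), drawn to scale, with day 2 in blue, day 30 in red and the number of peaks at the right. The Foxa3 day 2 list has 92 peaks and the Hnf4a day 30 list 74, while 5 lists have 0.

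All peaks together formed 4047 merged regions, of which 3457 were in a single list and 590 in 2 or more. Regions of Foxa1 alone made up 3148 of them (77.8%). There were 377 regions of Hnf4a alone, 127 of Foxa3 alone and 19 of Foxa2 alone. All 3 Foxa proteins were listed on day 30 at 38 regions and on day 2 at 1. Of the 30 regions in 4 or more lists, 1 included Hnf4a. A region on chromosome 4 (41577181 to 41577727) was in all 6 Foxa lists, with scores from 5.28 for Foxa3 day 2 to 54.9 for Foxa1 day 30. The named regions on chromosomes 10 and 13 were in 5 Foxa lists each, without Foxa3 day 2.

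Chromosome X carried few peaks in most lists. It makes up 6.35% of the length and held 29 of the 3331 Foxa1 day 30 peaks (0.871%, 0.584 to 1.25%). In the Foxa1 day 2 list it held 1 of 442 and in the Hnf4a day 30 list 3 of 448 (0.670%, 0.138 to 1.94%). The exception was the Hnf4a day 2 list, with 3 of its 10 peaks on X (30%, 6.67 to 65.2%).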

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

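In the full lists, the share of day 2 peaks listed again on day 30 differed between factors, by two-sided Fisher's exact tests on peaks that were chosen after the shares were seen, as were the tests on the increase by day 30. The share was higher for Foxa1 than for Foxa2 by 22.8 percentage points (adjusted exact p = 0.0406), than for Foxa3 by 52.1 points (3.65e-28) and than for Hnf4a by 70.6 points (1.94e-05). It was higher for Foxa2 than for Foxa3 by 29.3 points (0.0104) and than for Hnf4a by 47.8 points (0.0193). Foxa3 over Hnf4a, at 18.5 points, was not past the threshold (adjusted exact p = 0.212). Neighbouring peaks in a block are not independent, so these p-values are too small, and each factor had 1 sample per day. The length of the lists enters these shares, and the order of the factors changed with it. With each day 30 list reduced to its day 2 number of peaks by score, the lists still differed in length, from 442 for Foxa1 to 10 for Hnf4a. Foxa1 was then higher than Foxa3 by 23.4 points (adjusted exact p = 8.18e-07) and than Hnf4a by 40.5 points (0.0223). The differences not past the threshold were 18.8 points for Foxa1 over Foxa2 (adjusted exact p = 0.165), 4.62 for Foxa2 over Foxa3 (0.565) and 21.7 for Foxa2 over Hnf4a (0.437). With every day 30 list reduced to the 174 highest-scoring peaks, the Foxa1 share was 22.6%, and Foxa1 minus Foxa2 turned to -25.2 points (adjusted exact p = 0.0258). Foxa1 over Foxa3 was then 5.50 points (adjusted exact p = 0.239) and over Hnf4a 22.6 points (0.190), while Foxa2 over Foxa3 (30.7 points, 0.0122) and over Hnf4a (47.8 points, 0.0258) passed. That setting caps the share of Foxa1, whose day 2 list is longer than 174, so neither setting removes list length. The Foxa3 share also rests on few places. Without the 2 densest blocks it was 57.4% of 47 peaks, a rise that the setting makes by its construction. Foxa1 was then higher by 13.9 points (adjusted exact p = 0.0768), the difference between Foxa2 and Foxa3 turned to -9.62 points (0.610), and Foxa3 over Hnf4a was 57.4 points (0.00267), which for the same reason is no call. Without all 9 dense blocks Foxa1 was higher than Foxa3 by 27.2 points (adjusted exact p = 0.005), Foxa2 than Foxa3 by 3.71 points (0.794) and Foxa3 than Hnf4a by 44.1 points (0.0184, with most of the same peaks removed). Without recurrent regions Foxa1 was higher than Foxa2 by 30.4 points (adjusted exact p = 0.0628), and Foxa2 higher than Foxa3 by 8.03 points (0.746) and than Hnf4a by 38.5 points (0.192).

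More peaks were listed on day 30 for Foxa1 and Foxa2, and depth and the threshold were weighed against a change in binding. The background rate read from the scores, per base of the shortest peak, was 1.10 times as high on day 30 as on day 2 for Foxa1 and 0.915 times for Foxa2, but depth stays open. The rate assumes that the shortest peak is the fragment length, which a match of widths to scores bore out in both day 30 lists and in neither day 2 list, and how the inputs entered the calling is not given. At the stricter threshold the count ratio was 26.4 for Foxa1 (exact counting interval 17.7 to 41.1). This argues against an excess made only of peaks just over the threshold. The cutoff was the same for lists of unknown depth, so greater depth on day 30 could raise this ratio too. For Foxa2 the ratio was 5 from 10 against 2 peaks (1.07 to 46.9), so an excess of marginal peaks stays open there. Judging this ratio by its interval was decided after it was seen. A difference in antibody yield, factor level or cell state between days was not tested and stays open.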

How the results depend on the processing

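Of 234 alternative values, 188 kept their direction and side of the threshold or moved little. Of the rest, 21 moved, 19 were no longer past the threshold, 3 newly passed it and 3 reversed. Among 130 for overlaps, 120 were the same, which means only that the permutation p stayed on its side of the threshold. Their shares could change in either direction. Foxa3 day 2 in Hnf4a day 30 fell from 49.3% to 10.6% without the 2 densest blocks. Foxa3 day 2 in Foxa3 day 30 rose from 18.5% to 44.1% without dense blocks. The Hnf4a day 2 values among them stayed at 0%, with no overlap to lose. Removal of dense blocks and of the 2 densest blocks was chosen after the data were seen. The stricter threshold left 25, 2, 2 and 5 day 2 peaks and 660, 10, 45 and 1 day 30 peaks for Foxa1, Foxa2, Foxa3 and Hnf4a. The Hnf4a count ratio thereby reversed to 0.2. At that threshold 0% of Foxa3 day 2 peaks overlapped Foxa1, 0% of Foxa2 day 2 peaks Foxa3, 0% of Hnf4a day 30 peaks Foxa1 and 0% of Foxa2 day 30 peaks Foxa3, from 2, 2, 1 and 10 peaks. Foxa3 day 2 counts were 64 with near peaks merged, 69 without recurrent regions, 34 without dense blocks and 47 without the 2 densest. Without recurrent regions, 13 Foxa2 and 6 Hnf4a day 2 peaks were left. Without regions in 4 or more lists, 0% of Foxa2 day 2 peaks overlapped Foxa1 or Foxa3; that setting removes regions for being shared, so it tests little. With equal numbers, 0% of Foxa2 day 2 peaks overlapped Foxa3. Overlap of Hnf4a with Foxa1 on day 30 was 0.224% without regions in 4 or more lists (permutation p by placement = 0.142) and 0.328% without dense blocks (0.102). With centres within 500 bp, 1.15% of Foxa2 day 30 peaks met Hnf4a (0.001, the smallest possible). The difference of Foxa2 over Foxa3 in share listed again reversed to -9.62 points without the 2 densest blocks, since these hold no day 30 Foxa3 peak. Without recurrent regions, the difference of Foxa1 over Foxa2 grew to 30.4 points but, with 13 Foxa2 peaks, its adjusted exact p was 0.0628; Foxa2 over Hnf4a and over Foxa3 had 0.192 and 0.746. With day 30 lists reduced to the day 2 number, a setting chosen after the data were seen, 3 of these 5 calls were lost. With every day 30 list reduced to 174 peaks, also chosen then, Foxa1 minus Foxa2 reversed to -25.2 points and 2 calls were lost; fewer day 30 peaks than Foxa1 day 2 peaks were left by construction. Where fewer peaks were left, that is the construction of the setting; beyond this the cause was not tested. Leaving out mitochondrial, random and unplaced sequences moved nothing, as no peak lies there. Analyses of start sites, motifs and gene lists were not run. No replicate numbers pair the samples; paired by factor, the day test of counts gave an exact p of 0.375 at the stricter threshold, with 3 of 4 ratios above 1. Depth, unknown here, limits how many weak sites each list can hold.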

Other observations

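The tests in this part were chosen after the patterns were seen. The Foxa3 day 2 peaks that were listed again gathered in a few places. Blocks of 5 or more Foxa3 peaks with peaks of both days, 1 on chromosome 1, 3 on chromosome 11 and 1 on chromosome 12, held 20 of the 27. Peaks of both days were a condition for these blocks, so the count describes where sharing lay and does not test it. These 5 blocks held no Foxa1 or Foxa2 peak of either day, but 3 of them held Hnf4a day 30 peaks (1, 2 and 1). The merged regions of the first and the third strongest Foxa3 day 2 peaks, in the blocks described next, included Hnf4a day 30. Of the 27 peaks, 4 overlapped a Foxa1 list. The block on chromosome 12 (55797677 to 55839773) had 7 Foxa3 peaks on day 2 and 6 on day 30. The block on chromosome 11 from 101488561 to 101519995 had 6 and 4, and that on chromosome 1 (72272853 to 72301990) had 5 and 2.

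Hnf4a day 30 peaks were clustered too. In 9 blocks of 5 or more Hnf4a peaks lay 160 peaks, 35.7% of the list. A block on chromosome 6 (52173051 to 52190430) held 19 Hnf4a peaks and no Foxa peak. One on chromosome 11 (120091618 to 120099287) held 18, with 1 Foxa1 and 1 Foxa3 day 30 peak. One on chromosome 5 (143574274 to 143585201) held 15. It contained the single region in 4 or more lists that included Hnf4a (143582248 to 143582745), where Foxa1 was listed on both days and Foxa2 on day 30.

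Of the 10 Hnf4a day 2 peaks, 4 overlapped the Foxa2 day 30 list and no other list (40%, 12.2 to 73.8%; adjusted permutation p by placement = 0.002). They lay on chromosomes 12 (45166371 to 45166432), 14 (15950731 to 15950804), 2 (23657172 to 23657228) and X (159521403 to 159521463). All 10 peaks were 57 to 74 bp wide. The 4 that overlapped Foxa2 day 30 had Hnf4a scores above the stricter threshold of 15.07, which 5 Hnf4a day 2 peaks passed. The reversed Hnf4a count ratio at that threshold therefore rests mostly on them. The Hnf4a day 2 scores of the 4 were 16.8 to 21.2 and their Foxa2 day 30 scores 14.0 to 15.3. Of the 174 Foxa2 day 30 peaks, 156 were in a Foxa1 list, and these 4 were not. Random placement gave at most 0 overlaps for this pair, so any shared peak would pass. The placement test cannot tell sites shared by both factors from narrow pile-ups of reads, and both stay open.

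The overlap of Foxa3 day 2 with Hnf4a day 30 may come from reads piled up in dense blocks. Of the 72 overlapping peaks, 94.4% lay in dense blocks, 61 of them in the block at the start of chromosome 9. The blocks were defined after the clustering was seen, so this describes the pattern more than it tests it. Outside the blocks 4 overlapping peaks remained, and the highest of 1000 placements gave 1. Placement over whole chromosomes gave a mean of 0.001, so almost any overlap exceeds it. It cannot tell sites shared by both factors from smaller pile-ups of reads, and both stay open for that small part. Whether the blocks hold repeats or extra copies that the inputs did not balance was not tested.

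The low count on X in the Foxa1 day 30 list was set against copy number, since a single X per cell would lower pileups; the sex of the embryos is not given in the labels. Length alone, scaled from the 3302 autosomal peaks of the list, predicted 223.9 X peaks. If X pileups were lowered to those of a single copy, 59.9 were predicted, and 29 were observed (exact counting interval 19.4 to 41.7), below both. The prediction assumes that every peak sits on the background rate, and how to read a value below it was settled after both numbers were known, so copy number as part of the cause cannot be told apart from fewer X sites.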
